A study of Mus musculus with 6 samples.

How the data were processed

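Gene expression was measured in total RNA from mouse cells that the labels describe as immortalized limb mesenchyme, in 3 samples labelled anterior and 3 labelled posterior. Per the labels, the lines come from embryonic day 10.5 and carry a temperature-sensitive form of the SV40 T antigen, a viral protein that keeps cells dividing. Per the labels' protocols, RNA was extracted with Trizol, treated with DNase, cleaned on a column and amplified into biotinylated cRNA with an Illumina kit. Each sample was read on 1 mouse bead array with 1 colour. No label says that the samples of a line came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

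The deposited signal table held a linear intensity for each of 45281 probes on each array. Undetected probes lay at a common positive level and the array means differed, so these values were neither background subtracted nor normalized between arrays. The same deposited table gave a detection p-value for each probe and array, per the file headers. The authors' value table held log2 values of 18312 probes. The submitters' processing notes name limma without a version, and the scanner software is not given in the sources used here. Set against the deposited intensities, the authors' log2 values equal the quantile-normalized log2 intensities of those probes, without background correction, to within 5e-09. The table held each probe with a detection p-value under 0.01 on at least 1 array, and no others. Its scale is therefore log2 intensity without centring, and every array has a median of 7.06.

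The intensities were normalized with neqc of limma 3.58.1 in R 4.3.3. It estimates the background of each array from the detection p-values, corrects it with the normexp model, adds an offset of 16, takes log2 and applies quantile normalization. The offset makes the fold changes of dim probes smaller than they are. Probes with a detection p-value under 0.05 on at least 3 of the 6 arrays were tested, 18242 in all. The groups were compared with lmFit and eBayes of limma, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05 on the adjusted p. Of the tested probes 7762 passed, 3865 of them higher and 3897 lower. Differences are posterior minus anterior on the log2 scale, with the standard error of the fit (SE).

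Gene names came from the platform annotation of the probes in the authors' table, of which 15550 had 1 symbol, 9 had several and 2753 had none. The gene identifiers of 15537 were found in the RefSeq table, and 0 symbols changed. Among tested probes 14884 had a gene name. Of the 3358 without one, 1013 passed. List members without a named probe are not named here, which does not mean undetected. A gene was represented by its tested probe with the highest mean level, giving 9908 genes. Of 3560 genes with several tested probes, 22 had probes past the threshold in opposite directions, Actb among them, and 1041 had some past it and others not.

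A probe detected on none of the 3 arrays of a group has only a bound there. Its fold is given as "at least", from the bright group's mean against the dim group's mean of, per array, the higher of the lowest detected signal and the probe's own value, on normalized log2 values. The lowest detected signals lay between 4.70 and 4.91 on the 6 arrays.

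Before the data were examined, 50 gene lists, the design, the alternatives and the rule for named genes were fixed. The 44 lists with at least 5 tested genes were tested with camera of limma at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over these lists. Camera with an estimated correlation was run beside it, and fry, which tests whether the genes of a list move, on balance, one way. A further 5 lists were written after the leading genes had been seen and were adjusted as a family of their own. The first holds pluripotency genes from those leading genes. The values of the second, with further pluripotency genes, had not been seen when it was written.

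The rule names the 12 genes with the largest change in each direction among genes past the threshold that were detected on at least 2 arrays of each group and whose groups do not overlap. It adds the 6 largest bounds in each direction, measured members of the Hox, anterior and posterior limb bud, limb identity and sex-linked lists, and up to 4 leading members of every other list. Members of the added lists, and genes marked so, were named after their values were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

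The steps were tested on simulated data with 200 changed probes and a shifted list. In the real data 7762 of 18242 tested probes passed. The rates below therefore describe a comparison with far fewer changes and are not the rates of this one. In a first simulation undetected probes kept their fitted level, and the noise of the fit was added to the background noise. With 23972 probes tested, 1.49%, 38.8% and 87.9% of changes of 0.5, 1 and 2 log2 units were recovered, and 6.32% of calls were false. The simulation was revised after these values were seen, with no signal in undetected probes and the fit's noise limited to that of bright probes. With 18132 probes tested, recovery was then 7.46%, 70.1% and 97.0%, and 0.775% of calls were false. The simulations differed in both respects and in the probes tested, so the difference in recovery is not put down to 1 of them. Both simulations called the shifted list and 0 of 9 unshifted lists with camera.

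Detected probes numbered 16052 to 18657 on an array, and the number of arrays limits the precision. Alternatives changed the background correction, the normalization, the source of the values, the filter on dim probes, the variance model, the rule for several probes, the list test and the arrays used, and added the replicate number as a block. The slide as a block was not run, since the files name no slide. Leaving out arrays was first computed with the detection filter recomputed on the others. After those values were seen, it was also computed with the full set of tested probes, so this second version was chosen after seeing the data. It is the version given where no filter is named, and calls that change only with the filter recomputed are given beside it.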

Results

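Expression was compared between cells labelled as derived from the anterior and from the posterior limb bud of the mouse, with 3 arrays in each group. The labels state the comparison of these lines as the aim and give no narrower question. The libraries labelled anterior had 16052, 16916 and 17705 detected probes, and those labelled posterior had 18657, 17784 and 18025. Arrays of 1 group correlated at 0.971 to 0.989 across the tested probes, and arrays of different groups at 0.882 to 0.905. Probes are not independent replicates, so these correlations only describe the arrays. Levels below are normalized log2 intensities, given as mean ± SD over the 3 arrays of a group, and "higher" or "lower" means in the libraries labelled posterior.

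Genes known from pluripotent stem cells were brighter in the libraries labelled anterior, and Hox, Meis and retinoic acid genes in those labelled posterior. Many pluripotency genes were not absent from posterior, since 25 of 29 in the further list were detected on all posterior arrays. The labels describe limb mesenchyme, so it is in doubt whether the arrays hold the cells that they name. Pou5f1, which encodes the stem cell factor OCT4, lay at 11.62 ± 0.12 (SD, n = 3) in anterior and 6.82 ± 0.43 (SD, n = 3) in posterior, 27.8-fold lower. Igf2, an imprinted growth factor gene, lay at 7.53 ± 0.12 (SD, n = 3) in anterior and 13.39 ± 0.32 (SD, n = 3) in posterior, 58.3-fold higher. In the limma fit 4699 of 9908 genes (47.4%) passed the threshold, 2571 of them higher and 2128 lower. Changes of at least 2-fold were found in 1157 genes that were higher and 776 that were lower.

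The next genes were ranked among those past the threshold that were detected on at least 2 arrays of each group and whose groups do not overlap. Among them the 12 largest increases were those of Igf2, Crabp2, Meis2, Meis1, Peg3, Shd, Plat, Krt18, Synpo, Hmgn3, Cpm and Rec8. Crabp2, whose protein binds retinoic acid in the cytoplasm, was 52.4-fold higher (log2 5.71, SE 0.18). The homeobox genes Meis2 and Meis1 were 43.3-fold and 39.8-fold higher, and the imprinted zinc finger gene Peg3 26.9-fold. With the mean of its probes the log2 change of Meis2 was 3.0, against 5.44 here. Plat, the tissue plasminogen activator gene, was 21.8-fold higher, and the keratin gene Krt18 19.7-fold. The anterior libraries detected Crabp2, Meis1 and Plat on 2 of 3 arrays. Under the same limits on detection and overlap, the 12 largest decreases were those of Trh, Lefty2, Pou5f1, Liph, Lgals3, Stmn2, Gtsf1l, Enox1, Esrrb, Krt42, Msc and Cpsf4l. Trh, which encodes the precursor of thyrotropin-releasing hormone, was 52.7-fold lower (log2 -5.72, SE 0.38). The Nodal antagonist gene Lefty2, detected on 2 of 3 posterior arrays, was 31.5-fold lower, and the orphan nuclear receptor gene Esrrb 21.6-fold lower. Adjusted p of these 24 genes in the limma fit was at most 1.24e-05.

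Other genes were not well above background on any array of 1 group, among them 473 that were higher and 117 that were lower. Such genes passed the detection filter only through the other group, so list counts that include them are no independent evidence of a direction. Pmp22, a myelin protein gene, was at least 83.5-fold higher, and Igfbp5, whose protein binds insulin-like growth factors, at least 75.9-fold. Hoxb2, Hoxb5, Tshz1 and Hoxa5 were at least 64.5-fold, at least 58.9-fold, at least 56.0-fold and at least 46.2-fold higher. Otx2, a homeobox gene of the epiblast and forebrain, was at least 28.0-fold lower. Ly6g6e, Slc28a1, Nphs1, Spry4 and Olfr985 were at least 16.8-fold, at least 16.2-fold, at least 12.1-fold, at least 10.2-fold and at least 9.97-fold lower. Sizes depend on how dim signals are processed. At least 2-fold changes were found in 946 genes without background correction, 1190 with a larger offset and 1082 in the authors' values, against 1933. The authors' values also cover other probes, with 10252 genes tested against 9908. Scaling the arrays to a common median moved the median of all genes by 0.17, and 72.1% of the 3532 genes then past the threshold were higher, against 54.7% here.

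Pluripotency genes were lower nearly as a whole, in 2 lists written after the leading genes had been seen. All 11 genes of the first list were lower, but they were picked from these values, so their count is no independent evidence of a direction. Tcl1 lay at 10.63 ± 0.19 (SD, n = 3) in anterior and at 4.66 ± 0.13 (SD, n = 3) in posterior, where 1 of 3 arrays detected it, and Zfp42 (REX1) was lower (log2 -4.09, SE 0.16). Of 29 further pluripotency genes, 24 were lower, 1 was higher and 4 did not pass, with 26 past the threshold adjusted over the list alone. Their median log2 was -2.44, or -2.14 with undetected genes at their bound. Nanog was 10.1-fold lower (log2 -3.33, SE 0.19), Klf5 9.15-fold and Sox2 7.65-fold, while Gbx2 was 3.68-fold higher. Of the 29 further genes, 25 were also detected on all posterior arrays. Dppa5a lay at 14.36 ± 0.02 (SD, n = 3) in anterior and 13.60 ± 0.30 (SD, n = 3) in posterior, and posterior means of Dppa4, Dnmt3b and Dnmt3l were 11.17, 10.90 and 10.72. Slc2a3 and Sall4, at 12.09 and 11.44 in posterior, did not pass (adjusted p = 0.0907 and 0.0993). Slc2a3 passed as lower with the replicate block (0.0427), with trend and robust variances (0.0465) and without posterior replicate 3 (0.0375), and Sall4 without background correction (0.0476) and with trend and robust variances (0.0478). Camera gave adjusted p = 2.90e-13 for the further list, over the 5 added lists, and adjusted p = 0.0168 with an estimated correlation. No list test is given for the first list, because its genes were picked from these values.

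**Figure D1:**
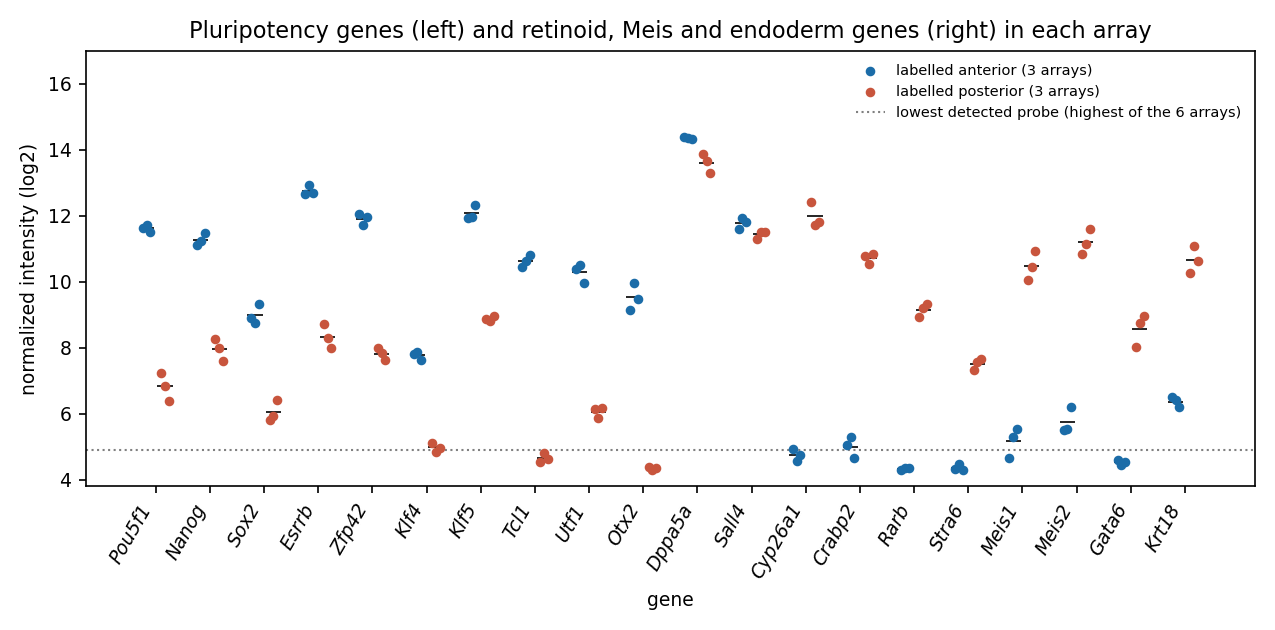
Normalized log2 intensity (vertical axis) of pluripotency genes on the left and of retinoid, Meis and endoderm genes on the right, in each library labelled anterior (blue) and posterior (red), with bars at the group means and a dotted line at the highest of the arrays' lowest detected signals. Pou5f1 has means of 11.62 in anterior and 6.82 in posterior, and Cyp26a1 of 4.74 and 11.99.

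Hox genes were higher in the libraries labelled posterior in each of the 4 clusters. Of the 21 tested Hox genes 16, among them 7 of the 8 HoxB genes, were detected on no anterior array. These were tested through the posterior arrays alone and could hardly have come out lower. The Hox counts and camera p-values are therefore no independent evidence of a direction. Camera gave adjusted p = 1.46e-06 for HoxB, 0.00233 for HoxA and 0.0125 for HoxD, and with an estimated correlation adjusted p = 0.447 for HoxB and HoxA, and adjusted p = 0.493 for HoxD. HoxD genes were chosen beforehand as a check on the labels, but among them it is the later genes of the cluster that mark the posterior limb bud. The 4 genes that passed lie earlier in it. Hoxd4 was at least 3.29-fold higher, Hoxd8 at least 3.02-fold, Hoxd9 at least 2.50-fold and Hoxd3 at least 1.34-fold, with no anterior array detecting them. Hoxd11, a later gene of the cluster, was detected on 1 of 3 anterior and 2 of 3 posterior arrays, with means of 4.80 and 4.80 and adjusted p = 0.986, and the other HoxD genes are not named here. The rise, shared with the other clusters, therefore does not check the labels. All 8 measured HoxB genes were higher, among them Hoxb1 (at least 25.4-fold), Hoxb4 (at least 10.8-fold) and Hoxb3 (at least 1.78-fold). In HoxA, Hoxa2, Hoxa4 and Hoxa5 were at least 5.88-fold, at least 6.46-fold and at least 46.2-fold higher, Hoxa7, detected on 1 of 3 anterior arrays, was also higher (means of 4.87 and 7.82), and Hoxa13 had a log2 difference of -0.10 (SE 0.14). In HoxC, Hoxc9 was at least 20.6-fold higher and Hoxc6 at least 5.63-fold. Hoxc10, with means of 4.87 in anterior, where 1 of 3 arrays detected it, and 5.28 in posterior, passed only without anterior replicate 3 (adjusted p = 0.0176) or with array weights (0.0315). In these libraries Pou5f1 moved the other way, with means of 11.62 in anterior and 6.82 in posterior.

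Adjusted over the list alone, 4 of 5 HoxD, 4 of 5 HoxA, 8 of 8 HoxB and 2 of 3 HoxC genes passed, as over all probes. HoxC had too few genes for a list test. When the detection filter was applied to the remaining arrays after leaving out posterior replicate 1 or 3, no HoxD gene was tested, and without posterior replicate 2 the limma fit called 0 of 1. In each of these 3 cases HoxA and HoxB also had too few genes for a list test, and HoxD had too few without anterior replicate 3. Of 5 tested genes that flank HoxD, 1 was lower (1 adjusted over the list alone), and the list was not called (adjusted p = 0.884). This gene, Nfe2l2 (log2 -0.88, SE 0.21), no longer passed with arrays scaled to a common median (adjusted p = 0.113), and without anterior replicate 3 the flanking genes had 1 higher and 1 lower.

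**Figure D2:**
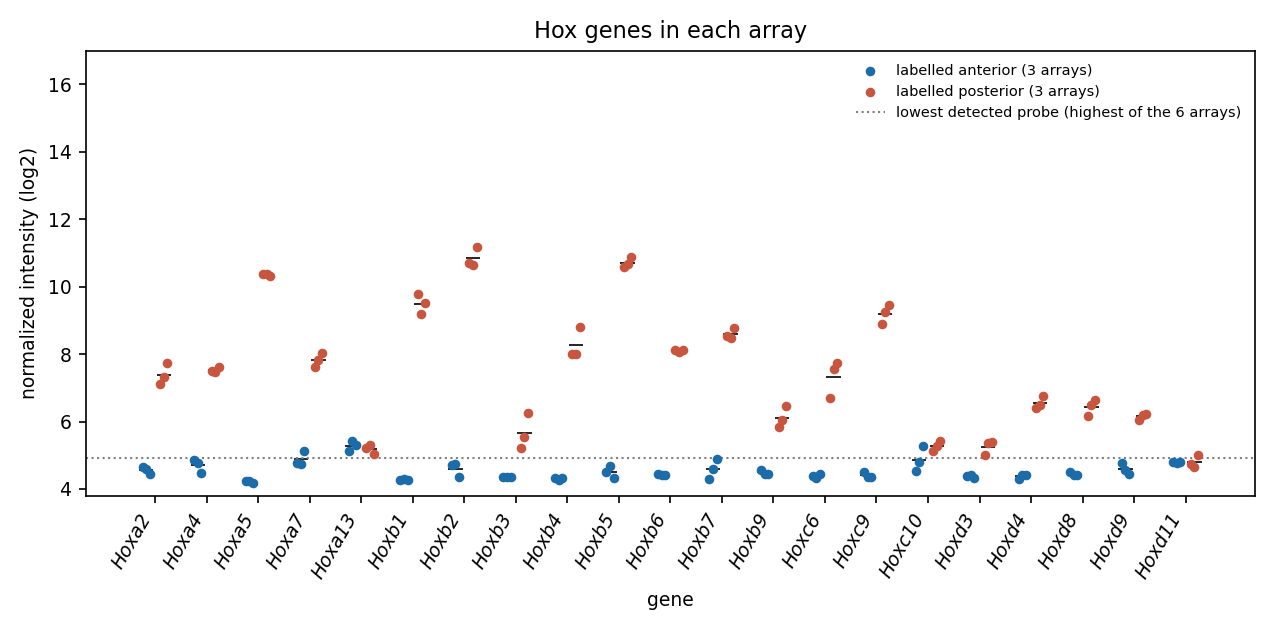
Normalized log2 intensity (vertical axis) of the tested Hox genes in each library labelled anterior (blue) and posterior (red), with bars at the group means and a dotted line at the highest of the arrays' lowest detected signals. Hoxb2, Hoxb5 and Hoxa5 have posterior means of 10.84, 10.71 and 10.36, and Hoxd11 has means of 4.80 in anterior and 4.80 in posterior.

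Genes of anterior limb identity were mostly higher in the libraries labelled posterior, 6 of 7, with 1 lower (7 adjusted over the list alone). Camera gave adjusted p = 0.0123, and adjusted p = 0.514 with an estimated correlation. Gli3, which encodes the repressor of Hedgehog signalling in the anterior limb bud, lay at 7.21 ± 0.17 (SD, n = 3) in anterior and 10.08 ± 0.28 (SD, n = 3) in posterior, 7.29-fold higher. Pkdcc was 11.2-fold higher with 2 of 3 anterior arrays detecting it, Irx3 7.88-fold and Cdon 2.55-fold. Irx5 and Alx4 were at least 1.98-fold and at least 1.42-fold higher, with no anterior array detecting them. Zic2 was lower, at 6.08 ± 0.13 (SD, n = 3) in anterior and 4.63 ± 0.21 (SD, n = 3) in posterior, where 1 of 3 arrays detected it. Taking the mean of its probes made its log2 change smaller by over 1.5 times.

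Genes of posterior limb identity went both ways, with 2 of 6 higher and 3 lower (5 adjusted over the list alone, camera adjusted p = 0.533). The 2 that were higher, Tbx2 and Shh, were detected on no anterior array and passed the detection filter only through posterior. With that filter recomputed, 0 genes were higher without any 1 posterior replicate. Then 3 of 3 were lower without posterior replicate 1, 2 of 4 without replicate 2 and 2 of 3 without replicate 3. Tbx2 was at least 1.77-fold higher. Shh, the signal of the posterior limb margin, was at least 1.08-fold higher, at 4.94 ± 0.08 (SD, n = 3) in posterior, near the detection limit. Tbx3 (log2 -1.66, SE 0.12) and Sall1 (log2 -1.19, SE 0.18) were lower. Ptch1, the Hedgehog receptor gene, was lower (log2 -0.60, SE 0.17) and no longer passed without posterior replicate 2 (adjusted p = 0.0534) or 3 (0.0658), with median scaling (0.340) or with the mean of its probes (0.139). In the Hedgehog list 8 of 11 genes were higher and 3 lower (11 adjusted over the list alone), without a list call (adjusted p = 0.0815), and 6 were higher and 1 lower without posterior replicate 2. Smo, the transducer of the pathway, was 3.42-fold higher, and Ccnd1 3.11-fold lower.

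All 8 of 8 tested proximal limb genes rose, with Meis2, Meis1 and Rarb in the lead (8 adjusted over the list alone). Of these 8, 2 were detected on no anterior array, Rarb among them, and could hardly have come out lower. With the detection filter recomputed, 5 of 6 were higher without posterior replicate 1, and 4 of 6 without posterior replicate 2 or 3. The list had adjusted p = 7.68e-05 with camera, and adjusted p = 0.493 with an estimated correlation. Of the tested genes 5 are also members of other fixed lists. Of 6 distal limb genes, Cyp26b1 (at least 5.06-fold) and Msx1 (4.29-fold) were higher and Bmp4 3.94-fold lower, without a list call (3 adjusted over the list alone, adjusted p = 0.695). Among 4 genes of forelimb and hindlimb identity, Hoxc9 and the hindlimb gene Tbx4 were higher (2 adjusted over the list alone). Tbx4 lay at 4.73 ± 0.14 (SD, n = 3) in anterior, where 1 of 3 arrays detected it, and at 6.07 ± 0.04 (SD, n = 3) in posterior, and Isl1 had a log2 difference of -0.05 (SE 0.19). Of 4 dorsal and ventral genes, 1 was higher, Wnt7a at at least 1.05-fold (1 adjusted over the list alone). Wnt7a no longer passed without anterior replicate 2 (adjusted p = 0.0527), posterior replicate 2 (0.0782) or posterior replicate 3 (0.0658), nor with median scaling, an offset of 50 or the authors' values. Without anterior replicate 3 that list had 1 higher and 1 lower.

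Retinoic acid genes were mostly higher in the libraries labelled posterior, and the list was called by camera (adjusted p = 4.41e-05) but not with an estimated correlation (adjusted p = 0.447). Of 14 genes 11 were higher, 1 was lower and 2 did not pass, with 12 past the threshold adjusted over the list alone. No anterior array detected 5 of the 14. With the detection filter recomputed without any 1 posterior replicate, 6 of 9 were higher and 1 lower. Of the 14 genes 4 are also in other fixed lists, among them Meis1, Meis2 and Rarb of the proximal limb list. Cyp26a1, which encodes an enzyme that degrades retinoic acid, lay at 4.74 ± 0.19 (SD, n = 3) in anterior, where 1 of 3 arrays detected it, and at 11.99 ± 0.38 (SD, n = 3) in posterior. The receptor gene Rarb was at least 19.8-fold higher, Crabp2 52.4-fold and Cyp26b1 at least 5.06-fold. The gene that was lower, Rarg, was singled out after its value was seen. The call was lost among genes detected on all 6 arrays (adjusted p = 0.184).

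Early limb mesenchyme genes were higher, and only 3 of 8 were detected on all anterior arrays. In total 6 of 8 were higher (6 adjusted over the list alone), with adjusted p = 0.0112 in camera and adjusted p = 0.493 with an estimated correlation. Msx1 was 4.29-fold higher, Pdgfra at least 3.03-fold and Twist1 2.94-fold. With the detection filter recomputed the list was not called without posterior replicate 2 (adjusted p = 0.123) or 3 (0.0803). In the same libraries Dppa5a had means of 14.36 in anterior and 13.60 in posterior. Of 14 smooth muscle and contractile genes 9 were higher (10 adjusted over the list alone), with adjusted p = 0.00233 in camera and adjusted p = 0.493 with an estimated correlation. Acta2, the smooth muscle actin gene, lay at 4.59 ± 0.25 (SD, n = 3) in anterior, where 1 of 3 arrays detected it, and at 10.18 ± 1.40 (SD, n = 3) in posterior. Its change on the log2 scale was smaller by over 1.5 times with the mean of its probes. Myl9 was at least 14.2-fold higher and Tpm1 6.30-fold higher.

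Markers of other cell types moved without a list call. Sox9, the regulator of cartilage formation, was at least 22.5-fold higher and the cartilage collagen gene Col2a1 11.9-fold, with 5 of 10 chondrogenic genes higher and 1 lower (adjusted p = 0.433). The change of Sox9 on the log2 scale was smaller by over 1.5 times with the mean of its probes. The keratin genes Krt18, Krt8 and Krt19 were 19.7-fold, 12.8-fold and at least 7.88-fold higher, and the ectoderm and apical ridge list had 7 of 13 genes higher and 4 lower (adjusted p = 0.466). Pecam1, expressed by endothelial and also by stem cells, was 8.11-fold lower, Vwf at least 3.42-fold lower and Flt1 at least 2.80-fold higher, with 2 of 7 endothelial genes higher and 3 lower (adjusted p = 0.265). With the detection filter recomputed the endothelial list was called as lower without posterior replicate 1 (0.0223), 2 (0.0249) or 3 (0.0278). In these cases 0 of 5 endothelial genes were higher, and 4, 3 and 3 were lower. Acta1 was at least 5.87-fold higher and Tnnt1 2.79-fold lower in the myogenic list, with 3 of 5 higher and 1 lower (adjusted p = 0.536). Of these 5 genes, 3 were detected on no anterior array. With the detection filter recomputed without any 1 posterior replicate, 2 myogenic genes were tested and 0 were higher. Then 1 was lower without posterior replicate 1 or 3, and 2 without posterior replicate 2. Scx was at least 2.57-fold higher in the tendon list, with 3 of 7 higher (adjusted p = 0.351). Dlk1 led the adipogenic list at 17.3-fold higher, with 4 of 7 higher and 1 lower (adjusted p = 0.169). Leaving out 1 array moved some of these counts: 4 chondrogenic genes were higher and 2 lower without anterior replicate 1, anterior replicate 3 or posterior replicate 3. Of myogenic genes 2 were lower without posterior replicate 2 and of tendon genes 2 without anterior replicate 3, and 0 adipogenic genes were lower without any 1 array but anterior replicate 1. With the filter recomputed without posterior replicate 1, 2 or 3, ectoderm genes had 4, 3 and 3 higher and 4, 3 and 5 lower. Chondrogenic genes then had 3, 2 and 2 higher and 1, 1 and 2 lower. Counts adjusted over the list alone were 6 chondrogenic, 11 ectoderm, 6 endothelial, 4 myogenic, 4 tendon and 5 adipogenic genes. Between these same libraries Pou5f1 was 27.8-fold lower.

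The neural crest, osteogenic and blood lists had too few genes for a list test. Of 4 neural crest genes 3 were higher and 1 lower (4 adjusted over the list alone), with Sox10 at least 2.11-fold higher, Mbp 2.48-fold and Ngfr 4.50-fold lower. Of 3 osteogenic genes, Dlx3 was 6.49-fold higher with 2 of 3 anterior arrays detecting it (1 higher, 1 lower, 2 adjusted over the list alone). The median of that list (-0.34) and its mean (0.58) differ in sign. Ifitm5, its lower gene, had a log2 difference of -0.63 and no longer passed without posterior replicate 2 (adjusted p = 0.0607) or with median scaling (0.248), nor without anterior replicate 1 with the detection filter recomputed (log2 -0.53). The tested blood gene, Cd14, was detected on 0 of 3 anterior arrays and had a mean of 4.85 in posterior, near the detection limit, and 0 genes passed with limma, 0 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone.

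Matrix, BMP, WNT and guidance genes were called as higher lists in camera (adjusted p = 0.00257, 0.00233, 0.0236 and 0.0125). With an estimated correlation none of the 4 was called, with adjusted p = 0.493 for matrix, BMP and guidance genes, and adjusted p = 0.572 for WNT genes. Of 17 matrix genes 12 were higher and 3 lower (17 adjusted over the list alone). Ecm1 was 14.2-fold higher (log2 3.83, SE 0.26, or 2.41 with the mean of its probes), and the basement membrane collagen genes Col4a2 and Col4a1 were 8.37-fold and 6.02-fold higher. Of 14 BMP genes 10 were higher and 1 lower (13 adjusted over the list alone), with Bmp1 9.78-fold higher and Bmp4 3.94-fold lower. Of 18 WNT genes 11 were higher and 2 lower (13 adjusted over the list alone), with the receptor gene Fzd2 higher (log2 4.09, SE 0.27) and the WNT inhibitor gene Notum 5.21-fold lower (log2 -2.38, or -1.57 with the mean of its probes). Of 12 guidance genes 8 were higher and 1 lower (9 adjusted over the list alone), with Plxna2 at least 13.9-fold and Nrp1 at least 6.95-fold higher. Among genes detected on all 6 arrays the BMP and WNT lists were not called (adjusted p = 0.0868 and 0.909). With the detection filter recomputed the WNT list was not called without anterior replicate 3 (0.0501) or posterior replicate 1 (0.0797), 2 (0.204) or 3 (0.230), nor the guidance list without posterior replicate 1 (0.159), 2 (0.375) or 3 (0.468).

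Of 13 FGF genes 6 were lower and 3 higher (11 adjusted over the list alone). The list was not called (adjusted p = 0.10) except with median scaling (0.0153). Etv5 lay at 10.16 ± 0.15 (SD, n = 3) in anterior and 6.09 ± 0.15 (SD, n = 3) in posterior, 16.8-fold lower. Etv4 was 11.7-fold lower with 2 of 3 posterior arrays detecting it, Dusp4 6.42-fold and Spry4 at least 10.2-fold. Of 13 proteases and inhibitors 6 were higher and 3 lower (9 adjusted over the list alone, adjusted p = 0.129), with Serpinf1 12.6-fold higher (log2 3.65, or 1.72 with the mean of its probes). That list was called with median scaling (0.0254). Of 14 TGF-beta and YAP targets 6 were higher (6 adjusted over the list alone, adjusted p = 0.0845), with Axl 3.63-fold higher, and the list was called without posterior replicate 1 (0.0426), with median scaling (0.0254) and with a detection p under 0.01 on all 3 arrays of a group (0.0233). Without anterior replicate 3 it had 6 higher and 1 lower. Of 11 Eph and ephrin genes 6 were higher and 1 lower (7 adjusted over the list alone, adjusted p = 0.210), with Efnb1 4.18-fold higher and Epha2 4.45-fold lower. Of 12 Notch genes 1 was higher and 3 lower (4 adjusted over the list alone, adjusted p = 0.464), with Notch4 4.76-fold lower. Leaving out anterior replicate 2 or posterior replicate 1 gave 2 higher and 1 lower, and leaving out posterior replicate 3 gave 1 and 1.

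Cell division genes were called as lower in camera (adjusted p = 0.0300), and inhibitor and senescence genes as higher (adjusted p = 0.00739). Neither list was called with an estimated correlation (adjusted p = 0.493 and 0.447). Of 28 cell division genes 12 were lower and the other 16 did not pass (13 adjusted over the list alone). E2f1, a transcription factor gene that activates genes of DNA synthesis, was 1.92-fold lower, and Mcm7 and Cdt1, which prepare replication origins, were 1.82-fold and 1.71-fold lower. The list call was also lost without posterior replicate 2 (adjusted p = 0.0522) and among genes detected on all 6 arrays (0.0868), and with the detection filter recomputed without posterior replicate 1 (0.0580), 2 (0.127) or 3 (0.0803). Of 11 inhibitor and senescence genes 8 were higher (9 adjusted over the list alone), with Cdkn1a (p21) 3.12-fold and Cdkn1c 2.24-fold higher. Of 18 p53 targets 6 were higher and 3 lower (10 adjusted over the list alone, adjusted p = 0.182), with Phlda3 3.02-fold higher, and that list was called among genes detected on all 6 arrays (0.0327).

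Imprinted genes and class I antigen presentation genes were called as higher lists in camera (adjusted p = 0.00233 and 0.000423), but not with an estimated correlation (adjusted p = 0.493 for both). Of 16 imprinted genes 10 were higher and 1 lower (11 adjusted over the list alone), with Igf2 58.3-fold, Peg3 26.9-fold, Dlk1 17.3-fold and Ndn 8.74-fold higher. Of 12 antigen presentation genes 10 were higher (11 adjusted over the list alone), with the peptide transporter gene Tap2 at least 4.55-fold and B2m 3.90-fold higher. Of 17 interferon-stimulated genes 7 were higher and 3 lower (13 adjusted over the list alone, adjusted p = 0.0756), with Gbp2 higher (log2 2.32, SE 0.21). That list was called without posterior replicate 2 (0.0190), and with the detection filter recomputed without anterior replicate 1 (0.0313) or 2 (0.0360). Of 7 chemokine and cytokine genes 3 were higher (4 adjusted over the list alone, adjusted p = 0.0701), with Cxcl10 at least 1.98-fold higher. That list was called without anterior replicate 2 (0.0493) or posterior replicate 3 (0.0367).

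Chromatin and reference genes went both ways and 0 ribosomal protein genes passed, without list calls. Of 26 Polycomb genes 8 were higher and 7 lower (18 adjusted over the list alone, adjusted p = 0.849), with Phc2 6.38-fold higher and Phc1 3.97-fold lower. Of 17 trithorax and demethylase genes 4 were higher and 5 lower (10 adjusted over the list alone, adjusted p = 0.536), with Smarca2 6.38-fold higher (log2 2.67, or 1.33 with the mean of its probes) and Ash2l 2.09-fold lower. The median of that list (-0.17) and its mean (0.02) differ in sign. Of 20 ribosomal protein genes 0 passed with limma, 2 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone (adjusted p = 0.501), while median scaling called the list as lower (0.0144) and 1 gene was lower without anterior replicate 3. Of 9 reference genes 2 were higher and 2 lower (4 adjusted over the list alone, adjusted p = 0.695). Gusb was 1.77-fold higher and Pgk1 1.62-fold lower. Without anterior replicate 1 or 2, or posterior replicate 2 or 3, 1 reference gene was higher and 1 lower.

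The calls of the other reference genes, Rpl13a (lower, log2 -0.46) and Actb (higher, log2 0.56), depended on the setting. Rpl13a no longer passed without anterior replicate 1 (adjusted p = 0.0864) or 2 (0.0694), without posterior replicate 2 (0.0900) or 3 (0.0867), or with median scaling (0.0754). Actb no longer passed without anterior replicate 1 (0.142) or 2 (0.0541), without posterior replicate 2 (0.138) or 3 (0.120), with median scaling (0.395), with cyclic loess (0.0504) or with no filter on dim probes (0.108). With the mean of its probes Actb was lower, at -0.64 (adjusted p = 0.0180).

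Stress and metabolic lists were not called, although several were under other settings. Of 15 heat shock genes 4 were higher and 4 lower (8 adjusted over the list alone, adjusted p = 0.536), with Hspb1 3.32-fold lower. Of 18 unfolded protein and amino acid stress genes 3 were higher and 7 lower (11 adjusted over the list alone, adjusted p = 0.190), with Chac1 8.77-fold lower and Atf3 at least 5.36-fold higher. Of 20 hypoxia and glycolysis genes 4 were higher and 7 lower (13 adjusted over the list alone, adjusted p = 0.115), with Pfkp 11.8-fold and Pdk1 6.39-fold lower. That list was called without anterior replicate 3 (0.0180), where 11 genes were lower, and with median scaling (0.0133). Of 15 sterol synthesis genes 7 were higher (7 adjusted over the list alone, adjusted p = 0.0701), with Msmo1 2.08-fold higher. The count was 3 higher without posterior replicate 2, and 3 higher and 1 lower without posterior replicate 3. That list was called without anterior replicate 1 (0.0375), anterior replicate 2 (0.0440) or posterior replicate 1 (0.0220), with the authors' values (0.0479) and among genes detected on all 6 arrays (0.0327). Of 16 immediate early genes 6 were higher and 6 lower (12 adjusted over the list alone, adjusted p = 0.787), with Fosl2 at least 5.56-fold higher and Klf2 13.3-fold lower, and that list was called among genes detected on all 6 arrays (0.0298).

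Sex-linked transcripts showed few differences. The Y-linked genes Eif2s3y and Uty were detected on all 6 arrays, with log2 differences of -0.63 (SE 0.31) and -0.17 (SE 0.17). Eif2s3y passed without anterior replicate 2 (log2 -0.87) or posterior replicate 1 (-0.94). Of 7 genes 2 were lower, Tsix and Eif2s3x (2 adjusted over the list alone, adjusted p = 0.293). Leaving out anterior replicate 2 gave 4 lower, and anterior replicate 3 or posterior replicate 2 or 3 gave 1. Tsix lay at 5.44 ± 0.31 (SD, n = 3) in anterior and at 4.63 ± 0.17 (SD, n = 3) in posterior, where 1 of 3 arrays detected it. Eif2s3x (log2 -0.45, SE 0.14) no longer passed without anterior replicate 3 (adjusted p = 0.0799) or posterior replicate 1 (0.0856), 2 (0.0557) or 3 (0.0965), with median scaling (0.253) or with cyclic loess (0.0513), nor without anterior replicate 2 with the detection filter recomputed (0.0505).

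Camera called 16 of the 44 tested lists, 15 as higher and 1 as lower. With an estimated correlation 0 of them were called, 4 had an unadjusted p under 0.05, and the lowest adjusted p = 0.447. The HoxA list had an estimated correlation of -0.14, yet its unadjusted camera p rose from 0.000376 to 0.0222. The lost calls are therefore not put down to correlation between genes alone. Fry called 34.

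**Figure D3:**
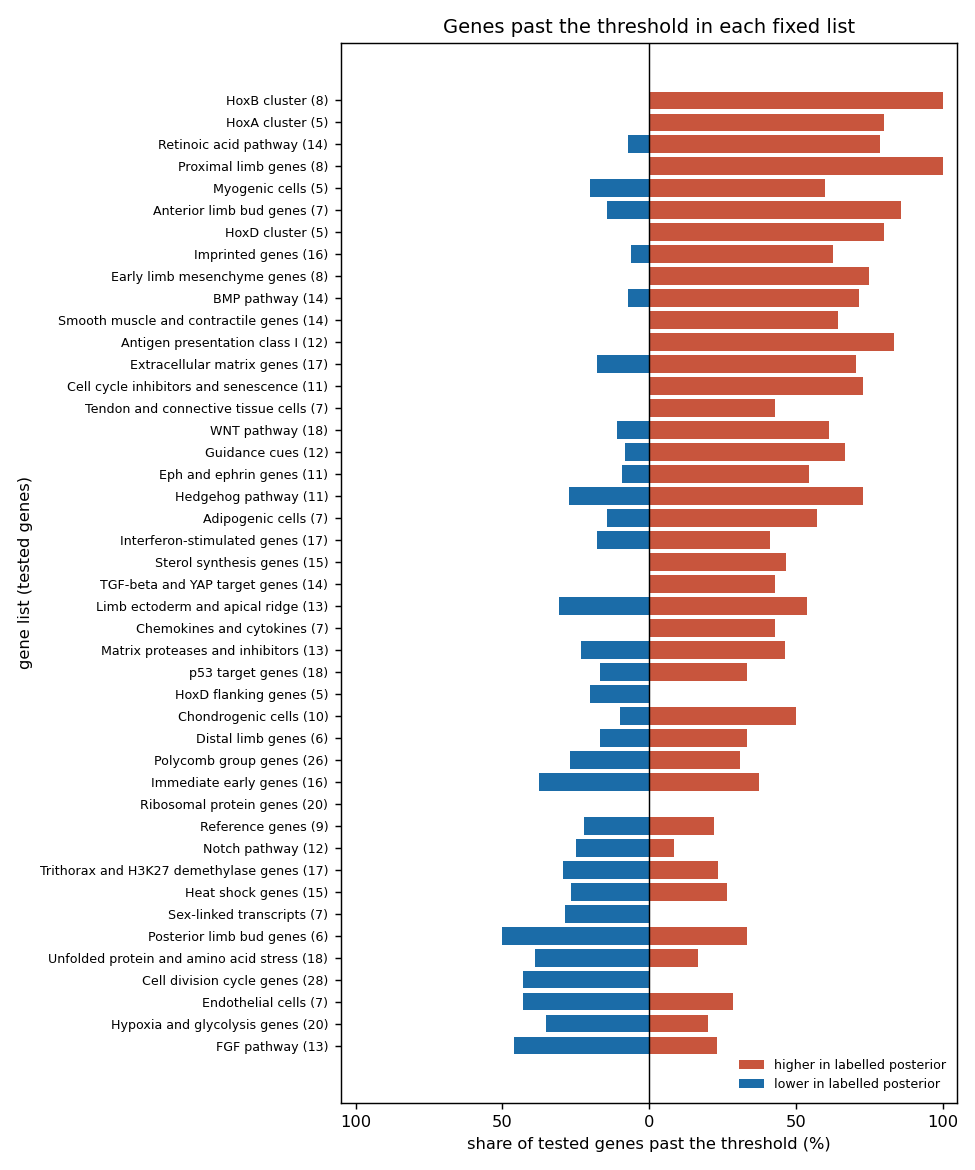
Share of tested genes past the threshold (horizontal axis, percent) in each of the 44 fixed lists with at least 5 tested genes, to the right for genes higher and to the left for genes lower in the libraries labelled posterior, with the number of tested genes in brackets. All 8 HoxB genes and all 8 proximal limb genes are higher, and 0 of 20 ribosomal protein genes pass. No anterior array detected 7 of these HoxB genes and 2 of these proximal limb genes.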

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

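Leaving out arrays with the full set of tested probes was chosen after seeing the data, since the version with the detection filter recomputed had been run first. Across 5889 values of the 261 named genes under alternatives, 5685 kept their direction and their side of the threshold, 181 lost the call, 22 gained one and 1 turned: Actb, at -0.64 with the mean of its probes. Genes changed at least 2-fold numbered 1933 of the 4699 past the threshold, and 946 without background correction, 1190 with an offset of 50, 1082 with the authors' values and 1179 with a detection p under 0.01 on all 6 arrays. The first 3 of these shrink the folds of dim probes by construction, and the last tests fewer genes. Of 238 named genes past the threshold, 121, 69 and 97 had a log2 change smaller by over 1.5 times under those first 3, and 17 with the mean of probes. Lists called numbered 16, and 8 with detection on all 6 arrays, where no HoxD gene was tested, 0 with an estimated correlation and 34 with fry, which asks another question. Without 1 replicate, and the full set of tested probes, 5991 to 7668 probes, 3696 to 4638 genes, 1867 to 2105 genes of at least 2-fold, 16 to 18 lists and 4 HoxD genes passed, and in 17 of 55 lists the count of genes higher or lower moved by over 1.5 times. With the filter recomputed, so that probes detected only in the shortened group drop out, the lowest counts were 5157 probes, 3192 genes, 1618 genes of at least 2-fold, 10 lists and 0 HoxD genes, all without posterior replicate 2, and 10 lists also without posterior replicate 3, and 43 of 55 lists had a count that moved by over 1.5 times. No HoxD gene was tested in that way without posterior replicate 1 or 3, and 63 of the 238 named genes past the threshold were not tested without any 1 of the posterior replicates. Median scaling called 5 further lists, and detection on all 6 arrays 3 further lists, while 4 of the 16 lost the call there and 7 had too few genes left for a test. With the replicate block 4744 genes passed. Arrays of the same number had deviations from their group means that correlated at 0.289, 0.162 and -0.08, and 3 of 6 arrays correlated best with their own number, so the numbers are not taken to pair the samples. Signal over background limits what dim genes show, and a slide block was not run because the files name no slide.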

Other observations

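The tests of probe identifiers, of a minor share, of limb position and of retinoic acid were chosen only after the result was seen, as were the lists of endoderm, neural and gastrulation genes. Endoderm genes were higher in the libraries labelled posterior, with 12 of 17 higher and 1 lower (13 adjusted over the list alone). Camera gave adjusted p = 0.000461 over the 5 added lists, and adjusted p = 0.287 with an estimated correlation. Gata6, a transcription factor gene of endoderm, was at least 13.4-fold higher, Dab2 was 4.75-fold higher and Apoe 4.84-fold lower. Of the tested genes 7 are also in fixed lists, and 2 were lower without anterior replicate 1.

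Neural genes went both ways, with 4 of 8 higher and 2 lower (6 adjusted over the list alone, adjusted p = 0.481). The counts were 2 higher and 2 lower without posterior replicate 2, and 4 higher and 1 lower without anterior replicate 1. Nes, the intermediate filament gene of neural progenitors, was 4.25-fold higher and Elavl3 2.73-fold lower. Of 5 gastrulation mesoderm genes 3 were higher and 1 lower (4 adjusted over the list alone, adjusted p = 0.333). Meox1 was at least 4.24-fold higher and Tcf15 9.54-fold lower.

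Pluripotency genes were bright in the libraries labelled anterior. Probes paired with the wrong genes are argued against, since the fold changes of a gene's 2 brightest probes correlated with Spearman's rho of 0.832 across 3560 genes, which are not independent replicates. RNA of pluripotent cells, and so cells or samples other than those the anterior labels name, is a candidate source, as a hypothesis: 24 of 29 further pluripotency genes were detected on all anterior arrays and were lower in posterior, and 4 of the 29 are also in fixed lists. Dppa5a, Dnmt3l and Pou5f1 had anterior means of 14.36, 12.80 and 11.62, while Pdgfra, a gene of limb mesenchyme, was detected on 0 of 3 anterior arrays, as were Hoxa5, Hoxb2, Hoxb5 and Hoxc9. A minor share of pluripotent cells among limb mesenchyme stays open by the test set for it, since 3 of 8 early limb mesenchyme genes were detected on all anterior arrays, between the bounds for either answer, although of 21 Hox genes, counted afterwards and not used as a test, 1 was detected on all anterior arrays and 16 on none.

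Hox, Meis and retinoid genes were bright in the libraries labelled posterior. Anterior to posterior position in the limb bud as the cause is argued against only for the anterior limb bud genes that anterior arrays detected. Of these, Gli3, Irx3, Cdon and Pkdcc were higher in posterior and Zic2 was lower. In total 1 of 7 called genes of that list was lower, but 2 of the 7, Irx5 and Alx4, were detected on no anterior array. These 2 passed the detection filter through posterior alone and could hardly have come out lower. Retinoic acid exposure or response in the libraries labelled posterior stays open, because the 7 of 7 called induced genes that were higher belong to the list that shows the pattern and do not test it. Cells or samples other than those the posterior labels name also stay open, and 25 of 29 further pluripotency genes were detected on all posterior arrays. Other differences between the lines that the labels name are untested.

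Gain or loss of a whole chromosome in a line was tested on the medians of 20 chromosomes. The largest departure from the median of all genes was 0.101 log2 units, below it, on chromosome 8 (538 genes, permutation p = 0.0025, 10000 permutations). Its adjusted permutation p was just under 0.05, the only 1 of the 20 to be so. The permutations drew random genes, which are not independent replicates, so these p-values do not measure the spread between arrays. This departure lies between the bounds set before, 0.1 and 0.2, so by these bounds a gain or loss cannot be told apart from none. No chromosome reached the 0.2 set for a gain or loss. The other 9 splits of the 6 arrays into groups of 3 called 0 genes with limma at most (372 at an unadjusted p under 0.05), against 4699, and 1 of 10 splits gave as many. The 10 splits are too few for a share under 0.05. Each of the other 9 also puts arrays of both labels into each group, so the labelled difference adds to the spread there. Few calls in them follow from this by construction and give no measure of chance.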
